A study of Mus musculus with 6 samples.

How the data were processed

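RNA sequencing of RAW264.7 cells was analysed in 6 libraries: 2 untreated controls, 2 given LPS at 10 ng/ml and 2 given LPS at the same dose plus Sal-B at 50 μmol/L. Per the labels, RNA was taken with Trizol, libraries were prepared with TruSeq and KAPA stranded kits after poly(A) selection or rRNA depletion, and sequencing was on an Illumina HiSeq instrument. The labels do not say which of the capture methods each library had. The FPKM values were made by the authors and used as deposited: per the labels, cutadapt, HISAT2 2.0.5, StringTie and the GRCm38 genome are named, and the file headers name the columns FPKM. No scaling between libraries is stated. The table held 10780 genes, all protein-coding, and from the values only genes whose highest group mean was 0.5 FPKM or more. Read counts were not used here.

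Values were turned into log2(FPKM + 1), and the 10014 genes with 1 FPKM or more in at least 2 libraries were tested. All 6 libraries entered a single linear model with 3 groups and 3 residual degrees of freedom (limma 3.58.1 in R 4.3.3, empirical Bayes with a trend). The 3 comparisons were LPS against control, LPS plus Sal-B against LPS, and LPS plus Sal-B against control, each with a two-sided test and Benjamini-Hochberg adjusted p < 0.05. Fixing 36 gene lists, the tests, the rule for named genes and most alternative settings came before the data were examined. Of these lists, 34 had at least 5 genes tested and were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over lists within a comparison. Camera with an estimated correlation and fry, which tests a list against no change rather than against the other genes, were the alternatives. With an estimated correlation camera uses the 3 residual degrees of freedom, and with the preset one nearly as many as genes tested.

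Named genes followed a rule. In each comparison these were the 10 largest rises and 10 largest falls among genes past the threshold whose libraries did not overlap between groups and whose higher group mean was at least 5 FPKM. For each list described, up to 4 members with the smallest p were named, and a core panel of inflammatory genes was named in full (9 of 11 rose and 1 fell with LPS, 1 rose and 6 fell with Sal-B against LPS). Some genes, such as Mmp13 and Ccl17, are among the 4 of lists whose results are not described. Other genes outside the rule are marked as chosen after their values were seen.

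The overlap of opposite changes was set against independent lists, against 100 simulated sets of unchanged groups that share the LPS libraries, and against fits with 1 LPS library per comparison. GC percent and transcript length came from GENCODE M21 for 9959 of the genes tested (99.5%). Alternatives changed the pseudocount, the filter, the scaling between libraries, the replicate block, the libraries in the model, the trend, the minimum fold, and the libraries included, 1 left out at a time. Scaling to the same total, a GC and length correction, the averaging of treated pairs and same-median gene lists were added after seeing the data.

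Data were simulated with the spread of these libraries, with 200 of 10014 genes changed by LPS and 200 by Sal-B. In the real comparisons 63.1%, 42.3% and 72.8% of genes were called, so the simulated shares are not the recovery or error rates of those calls. In the simulation, 2-fold changes were recovered in 61.6% of cases for LPS against control, 59.7% for LPS plus Sal-B against LPS and 72.1% for LPS plus Sal-B against control. Changes of 4-fold were recovered in 94.6%, 94.8% and 96.5%, and 13.2%, 1.03% and 9.66% of calls were false, the higher shares arising where the control pair, with its larger spread, was compared. For LPS plus Sal-B against LPS alone, a list shifted by 0.5 on the log2 scale was called in 20 of 20 runs, with 1 call among unchanged lists. Genes in these runs were drawn independently, whereas the estimated correlation within the real lists reached 0.864 (DNA replication and G1/S). The runs therefore do not show how often lists of correlated genes are called falsely.

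Depth was estimated from the spacing of low values times transcript length in 875 single-transcript genes. The estimate counts values near 1 or 2 steps, a form chosen after a first version had given an implausible step for LPS plus Sal-B replicate 2. With these depths, differences between replicates were compared with Poisson sampling in genes with at least 20 fragments per pair. More genes than sampling predicts lay beyond the 95% range in control (44.8%) and LPS (9.13%), and 4.48% did in LPS plus Sal-B. A chi-square test over all these genes departed from sampling alone in each pair (p of 7.17e-280 in LPS, 1.14e-227 in LPS plus Sal-B and smaller in control). These p-values rest on the estimated depths. In LPS plus Sal-B the median squared difference was 0.408 of the sampling value, less than independent sampling at that depth gives. The reference is therefore unsure for this pair, and no conclusion is drawn from its p. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for this step and for the figures.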

Results

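RAW264.7 cells, a mouse macrophage-like line, were compared in 3 groups by RNA sequencing: untreated control cells, cells given lipopolysaccharide (LPS, a bacterial cell wall component sensed through Tlr4) at 10 ng/ml, and cells given the same dose of LPS plus Sal-B at 50 μmol/L. The questions were which transcripts LPS changed and which of these changes differed when Sal-B was present. Each group held 2 libraries, numbered replicate 2 and replicate 3, and replicate 1 was not analysed here. No group was given Sal-B without LPS. The sources used here give no treatment time and do not spell out Sal-B. Expression was given as FPKM, fragments scaled to transcript length and library size, for 10780 protein-coding genes, of which 10014 reached 1 FPKM in at least 2 libraries and were tested.

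Between 8639 and 9847 genes stood at 1 FPKM or more in each library, and the FPKM total per library ran from 309767 to 374371. Read counts were not used here. The spacing of the low values of 875 single-transcript genes gave a rough depth of 6478000 to 8869000 fragments per library, rough because it rests on 26 to 57 low values per library, of which 8 to 21 lay at 1 or 2 steps and 29.7% to 41.3% lay within 0.05 of a whole number of steps. The 2 libraries of a group correlated across genes at r = 0.963 in control, 0.989 in LPS and 0.994 in LPS plus Sal-B, against 0.820 to 0.868 between control and treated libraries and 0.943 to 0.945 between the treated groups. The first principal component held 73.7% of the variance and separated control from treated libraries, and the second held 18.5%.

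The control pair differed more than the treated pairs. The SD of the log2 difference between replicates was 0.44 in control, 0.27 in LPS and 0.19 in LPS plus Sal-B, and 329, 123 and 65 genes differed more than 2-fold. Against the scatter that sampling of fragments alone would give at the estimated depth, the median squared difference was 6.352-fold in control, 1.193-fold in LPS and 0.408-fold in LPS plus Sal-B. The value for LPS plus Sal-B is less than sampling of independent libraries would give. Either the rough depth or the independence of this pair is therefore in doubt. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these libraries. Each library was counted as a replicate, and counts with each treated pair averaged to 1 sample are given beside the main ones.

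Secreted inflammatory mediators led the rises in LPS-treated cells. Csf3, which encodes the growth factor of granulocytes, stood near the floor in control cells and showed the largest rise among the named genes. The chemokine genes Ccl2, Ccl5, Ccl22 and Cxcl2, whose products attract monocytes, T cells and neutrophils, and the interleukin-1 genes Il1a and Il1b followed the same course. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, and Lcn2, an iron-scavenging antibacterial protein, were also higher. Genes needed for mitosis were lower, as were Tlr7, a sensor of single-stranded RNA, and several genes of the mitochondrial genome.

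Csf3 rose from 0.539 ± 0.104 (SD, n = 2) to 434 ± 0.872 FPKM (SD, n = 2), a log2 fold change of 8.14 ± 0.09 (SE; limma, adjusted p = 2.44e-06). Errors of group means are the SD of n = 2 libraries throughout, and errors of log2 fold changes are SE. Because the fold changes were taken on log2(FPKM + 1), they understate the ratio for genes that were low in 1 group. Ccl2 rose from 0.50 ± 0.164 to 327 ± 2.58 FPKM (log2 fold change 7.77 ± 0.11, adjusted p = 3.79e-06) and Ccl5 from 11.4 ± 0.698 to 2640 ± 69.3 (7.73 ± 0.08, adjusted p = 2.44e-06). Ccl22 rose by 7.74 ± 0.24, Csf2, the growth factor of granulocytes and macrophages, by 7.39 ± 0.16, and Ptgs2 by 6.56 ± 0.24. Il1b was listed at 0.0596 and 0 FPKM in the control libraries and reached 146 ± 0.808 (adjusted p = 3.28e-06), while Il1a rose from 0.621 ± 0.0473 to 203 ± 3.08 (adjusted p = 2.72e-06). Tnf rose from 19.5 ± 10.4 to 347 ± 4.95 FPKM (4.18 ± 0.34, adjusted p = 0.000438) and Il6, listed at 0 and 0.123 in control, reached 11.5 ± 2.55 (adjusted p = 0.000147).

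Cxcl2 and Lcn2 rose by 7.35 ± 0.78 and 6.27 ± 0.78, with the larger errors coming from the control pair. Cxcl2 read 12.0 FPKM in control replicate 2 and 1.18 in control replicate 3, and Lcn2 read 14.1 and 1.63. Acod1, which makes the antibacterial metabolite itaconate, read 35.9 and 4.53 in the control libraries and 400 ± 1.93 FPKM with LPS (4.81 ± 0.83, adjusted p = 0.00444). Nos2, the inducible nitric oxide synthase, rose from 8.80 ± 0.787 to 98.9 ± 2.56 FPKM (3.35 ± 0.09, adjusted p = 3.98e-05). Hmox1, which degrades heme, rose from 65.6 ± 4.75 to 429 ± 0.507 (2.69 ± 0.09, adjusted p = 6.54e-05). Lif, a cytokine of the interleukin-6 family, and Mmp9, a secreted gelatinase, rose by 4.76 ± 0.09 and 4.81 ± 0.08. Ccl12, Ccl17 and Mmp13 were listed at 0 in both control libraries and reached 9.26 ± 0.0124, 23.2 ± 2.01 and 5.5 ± 0.0616 FPKM with LPS (adjusted p = 3.98e-05, 3.98e-05 and 6.83e-05).

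The largest falls were led by Ranbp3l, from 76.7 ± 53.8 to 0.482 ± 0.0665 FPKM (−5.52 ± 0.47, adjusted p = 0.000523), although its control libraries differed, at 38.7 and 115. Olfr933, an odorant receptor gene, fell from 28.6 ± 7.54 to 0.300 ± 0.0491 FPKM (−4.49 ± 0.18). S1pr1, the receptor that guides cell exit along sphingosine 1-phosphate, fell by 3.91 ± 0.32, Cd24a, a glycosylated surface protein, by 3.95 ± 0.32, and Pdcd4, an inhibitor of translation, by 3.54 ± 0.28. Tlr7 fell from 39.8 ± 1.51 to 1.87 ± 0.402 FPKM (−3.83 ± 0.15, adjusted p = 0.000101) and Tlr13, which senses bacterial ribosomal RNA, from 14.6 ± 0.0238 to 0.480 ± 0.145 (−3.40 ± 0.12). Tlr4 itself read 1.19 and 6.60 FPKM in the control pair and 0.959 ± 0.251 with LPS (−1.07 ± 0.55, adjusted p = 0.142), and the change was −1.96 without control replicate 2 (adjusted p = 0.000579) but −0.17 without control replicate 3 (adjusted p = 0.320). Nlrp3, the sensor of an inflammasome, fell from 9.94 ± 0.124 to 4.63 ± 0.0871 (−0.96 ± 0.10, adjusted p = 0.000932).

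**Figure D1:**
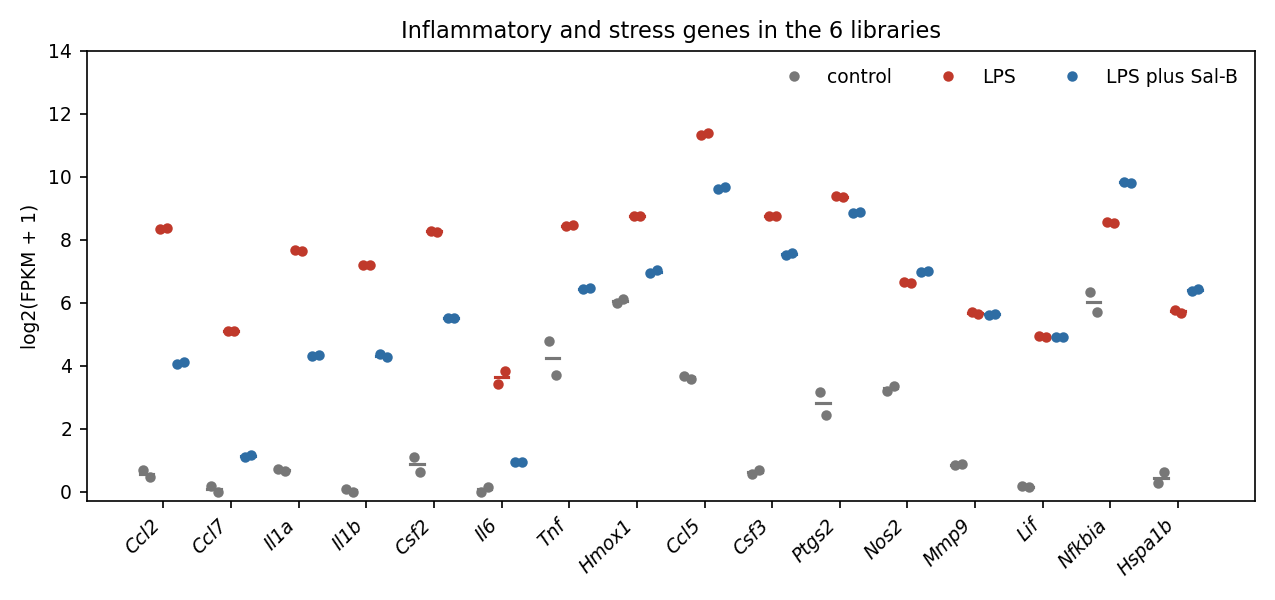
Expression of 16 inflammatory and stress genes in each of the 6 libraries, on the log2(FPKM + 1) scale. Bars mark the mean of the 2 libraries of a group, and on this scale Ccl2 fell most with Sal-B among the genes shown.

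Of 19 secreted cytokine genes tested, 18 rose and 0 fell with LPS, also 18 and 0 adjusted over the list alone (camera adjusted p = 3.10e-18, adjusted p = 0.122 with an estimated correlation). Of 15 chemokine genes 13 rose and 0 fell, 14 and 0 adjusted over the list alone (adjusted p = 9.30e-15, 0.229 with an estimated correlation). The type I interferon response, the antiviral program switched on through Irf7 and its relatives, had 37 of 40 genes up and 1 down, the same when adjusted over the list alone (adjusted p = 1.32e-24, 0.229 with an estimated correlation). Among its members Bst2, which tethers budding virus, rose by 2.26 ± 0.08, Irf7 by 4.62 ± 0.18, the DNA sensor gene Ifi204 by 2.37 ± 0.10 and the nucleic acid sensor gene Zbp1 by 4.10 ± 0.17. Regulators that feed back on NF-kB rose in 18 of 28 cases and fell in 1, or 19 and 1 adjusted over the list alone (adjusted p = 1.19e-13, 0.229 with an estimated correlation), with Gadd45b up by 4.01 ± 0.09 and Nfkbiz by 2.57 ± 0.11. Immediate early genes, which answer a stimulus without new protein, had 19 up and 5 down of 26, or 20 and 5 adjusted over the list alone (adjusted p = 9.48e-10, 0.138 with an estimated correlation), among them Myc at 2.45 ± 0.11 and Junb at 1.53 ± 0.09. No gene list of any comparison passed the threshold when the correlation between genes was estimated from these libraries. That form of camera has only 3 degrees of freedom here.

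All 40 genes of the mitosis list fell with LPS, also when adjusted over the list alone (camera adjusted p = 3.20e-09, adjusted p = 0.332 with an estimated correlation). Mki67, a marker of proliferating cells, fell from 73.4 ± 8.12 to 13.7 ± 0.0326 FPKM (−2.34 ± 0.10, adjusted p = 0.000144), Ccnb2, a cyclin of the entry into mitosis, by 1.89 ± 0.09, and Anln, which shapes the cleavage furrow, by 1.78 ± 0.09. Of 75 ribosomal protein genes 56 rose and 1 fell, 57 and 2 adjusted over the list alone (adjusted p = 4.05e-21, 0.393 with an estimated correlation), but quantile normalization left 19 up and 12 down. Nuclear genes of the respiratory chain had 20 up and 7 down of 49, or 18 and 6 adjusted over the list alone (adjusted p = 4.20e-06, 0.258 with an estimated correlation). Scaling to the same total flipped this split to 13 up and 16 down, while the same median gave 35 up and 1 down and quantile normalization 18 and 11. Cycs, the electron carrier cytochrome c, rose by 1.02 ± 0.11, and Sdha, the catalytic subunit of succinate dehydrogenase, fell by 1.34 ± 0.10.

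Of the 13 mitochondrially encoded genes 9 fell and 1 rose, the same when adjusted over the list alone (camera adjusted p = 0.0243, adjusted p = 0.414 with an estimated correlation). mt-Nd3, a subunit gene of complex I, fell from 1722 ± 48.4 to 125 ± 5.39 FPKM (−3.77 ± 0.08, adjusted p = 1.99e-05), mt-Nd4l by 2.42 ± 0.08, and mt-Cytb and mt-Nd1 by 2.36 ± 0.08 and 2.36 ± 0.09. The following 3 genes of this list were chosen after their values were seen. mt-Co3, a subunit gene of cytochrome c oxidase, rose by 0.33 ± 0.08 (adjusted p = 0.0143), but its adjusted p was 0.103 without LPS replicate 2, 0.122 without LPS replicate 3, 0.0578 without LPS plus Sal-B replicate 2 and 0.0580 without LPS plus Sal-B replicate 3. mt-Co1 stood at 0.35 ± 0.14 (adjusted p = 0.0659, and 0.00250 without control replicate 3). mt-Atp6 stood at −0.01 ± 0.08 (adjusted p = 0.938), but flipped with scaling, to 0.52 at the same median and −0.97 under quantile normalization. The 13 genes together made up 29.1% and 30.7% of FPKM in the control libraries, 18.1% and 18.8% with LPS and 26.0% and 25% with LPS plus Sal-B.

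**Figure D2:**
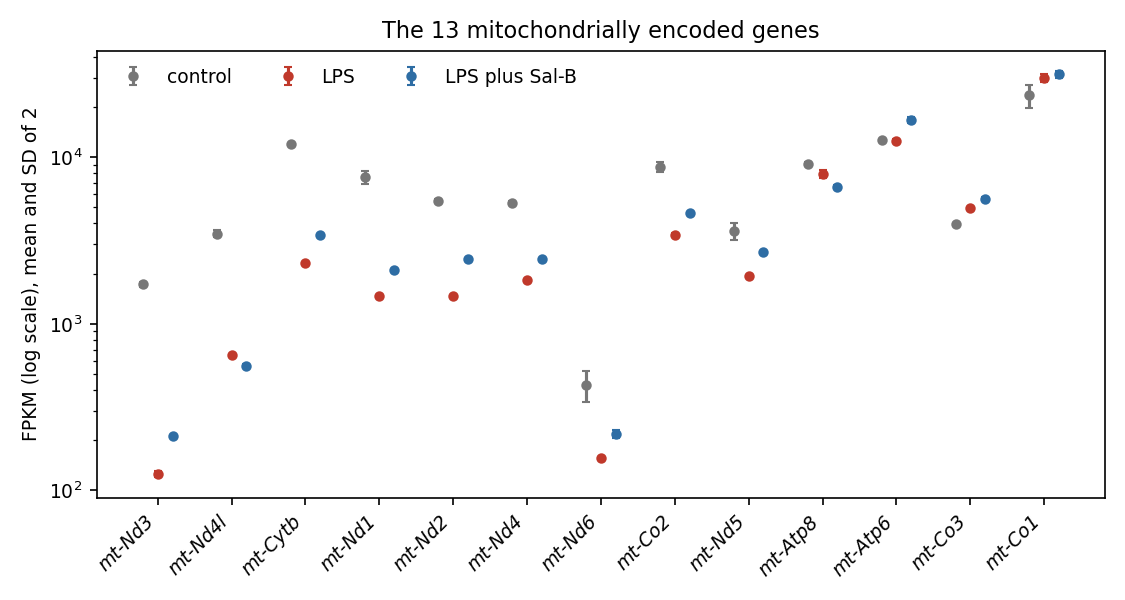
FPKM (mean ± SD, n = 2) of the 13 mitochondrially encoded genes in each group. With LPS mt-Nd3 fell most as a ratio to control, while mt-Atp6 stayed near its control level as deposited, higher at the same median and lower under quantile normalization.

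Across all genes, 1421 rose and 4898 fell with LPS (limma-trend, adjusted p < 0.05), of which 517 and 1920 changed at least 2-fold. The balance depended on scaling: at the same median of expressed genes 2962 rose and 2591 fell, and quantile normalization gave 2412 and 2661. The median log2 fold change of all genes was −0.40 as deposited and 0.03 at the same median, so a fall of this size was the typical change of a gene in the values as deposited. With each treated pair averaged to 1 sample 352 rose and 1255 fell.

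Sal-B together with LPS left many of the same mediators well below their level with LPS alone. The chemokine genes Ccl2 and Ccl7, which draw monocytes, and the interleukin-1 family genes Il1a, Il1b and Il1f6 were lower by the largest margins. Genes of the unfolded protein response, Xbp1 and Ddit3, were lower as well, as was Hmox1. Higher were Mef2c, a transcription factor of myeloid and muscle cells, Ccnd3, a cyclin of the G1 phase, and the checkpoint kinase gene Atr. Among the nuclear respiratory chain genes 40 of 49 were lower as deposited, fewer after scaling, and 8 of the 13 mitochondrially encoded genes were higher, but neither list passed with an estimated correlation.

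Ccl2 fell from 327 ± 2.58 to 16.0 ± 0.680 FPKM (−4.26 ± 0.11, adjusted p = 0.000260) and Ccl7 from 33.4 ± 0.433 to 1.21 ± 0.0664 (−3.96 ± 0.11, adjusted p = 0.000300). Il1a fell from 203 ± 3.08 to 19.0 ± 0.136 (−3.35 ± 0.08), Il1b from 146 ± 0.808 to 19.0 ± 1.11 (−2.88 ± 0.09) and Il1f6 from 15.8 ± 2.04 to 1.22 ± 0.129 (−2.92 ± 0.12). Csf2 fell from 307 ± 4.53 to 44.8 ± 0.384 FPKM (−2.75 ± 0.16), Il6 from 11.5 ± 2.55 to 0.916 ± 0.00751 (−2.69 ± 0.16) and Tnf from 347 ± 4.95 to 86.0 ± 1.29 (−2.0 ± 0.34, adjusted p = 0.00812). Ccl5 fell by 1.73 ± 0.08 and Cxcl10, a chemokine gene of the interferon response, by 0.73 ± 0.18 (adjusted p = 0.0235). Nos2 rose further, from 98.9 ± 2.56 to 126 ± 1.69 FPKM (0.35 ± 0.09, adjusted p = 0.0303). Ptgs2 stood at 462 ± 5.41 against 659 ± 10.6 FPKM (−0.51 ± 0.24, adjusted p = 0.135), Acod1 at 243 ± 2.96 against 400 ± 1.93 (−0.72 ± 0.83, adjusted p = 0.517) and Nlrp3 at 3.59 ± 0.375 against 4.63 ± 0.0871 (−0.30 ± 0.10, adjusted p = 0.0663). Tlr4 was at 0.244 ± 0.0377 against 0.959 ± 0.251 FPKM (−0.65 ± 0.55, adjusted p = 0.383). Errors of these fold changes pool the spread of all 3 groups, so the control pair enters them although it is not compared here. For Acod1 that pair read 35.9 and 4.53 FPKM. Without 1 of the LPS or LPS plus Sal-B libraries the adjusted p ran from 0.0530 to 0.0591 for Tnf, from 0.0905 to 0.121 for Cxcl10 and from 0.117 to 0.177 for Nos2. Without control replicate 2 or control replicate 3 it was 0.000488 and 0.000481 for Ptgs2, 0.000311 and 0.000284 for Acod1, 0.0361 and 0.0363 for Nlrp3, and 0.00884 and 0.00859 for Tlr4.

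LPS raised 34 genes to a mean of 10 FPKM or more from a control mean of at most 5% of that level. In these the share of the LPS increase left with Sal-B ran from 3.44% for Ccl7 to 182% for Hspa1a. The quartiles were 16.7%, 36.3% and 62.9%. Without a group given Sal-B alone, these shares do not tell an action on the LPS response from other effects of Sal-B. Ccl2 kept 4.77%, Il6 7.46%, Il1f6 7.72% and Il1a 9.09%, while Csf3 kept 42.9%, Ccl22 65.5%, Mmp9 97.7% and Lif 99.5%. Hspa1a and Hspa1b, near-identical heat shock genes between which fragments are hard to assign, and Phlda1 stood above their LPS level, at 182%, 162% and 115%.

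Xbp1, which drives the unfolded protein response, fell from 22.7 ± 0.496 to 2.5 ± 0.610 FPKM (−2.77 ± 0.17, adjusted p = 0.00138), and Ddit3, a stress factor that favours cell death, from 63.2 ± 1.62 to 7.96 ± 0.386 (−2.84 ± 0.60, adjusted p = 0.0159, but 0.0797 to 0.0841 without any 1 of the LPS or LPS plus Sal-B libraries). Scimp, an adaptor of Toll-like receptor signalling, fell by 2.72 ± 0.27, and Evi2, which overlaps the genes Evi2a and Evi2b on the same strand, by 3.65 ± 0.34. Egr1, an immediate early transcription factor, fell by 2.60 ± 0.26, and immediate early genes as a list had 16 of 26 down and 1 up, 17 and 1 adjusted over the list alone (camera adjusted p = 0.0128, adjusted p = 0.417 with an estimated correlation). Fcgr3, an activating receptor for antibody complexes, fell from 4.87 ± 0.149 to 0.421 ± 0.0207 FPKM (−2.05 ± 0.11) and Cd68, a lysosomal glycoprotein of macrophages, from 906 ± 12.6 to 394 ± 1.99 (−1.20 ± 0.07). Hmox1 fell from 429 ± 0.507 to 126 ± 5.70 (−1.76 ± 0.09) and the cystine transporter gene Slc7a11 from 4.15 ± 0.0470 to 0.426 ± 0.0376 (−1.85 ± 0.10).

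Zc3h11a showed the largest rise with Sal-B, from 2.64 ± 0.286 to 39.3 ± 0.110 FPKM (3.47 ± 0.40, adjusted p = 0.00319). Its locus holds other gene models on the same strand, among them Zbed6 (chosen after its values were seen, 0.52 ± 0.92, adjusted p = 0.676), so fragments could have been assigned differently between them. Mef2c rose from 2.85 ± 0.0250 to 20.7 ± 0.474 FPKM (2.49 ± 0.18), Ccnd3 from 1.92 ± 0.0116 to 12.1 ± 0.297 (2.16 ± 0.09), Gipr, the receptor of a gut hormone, by 2.05 ± 0.20 and Atr by 1.93 ± 0.10. Smc2, a condensin subunit gene, rose from 15.0 ± 0.309 to 59.3 ± 1.35 (1.92 ± 0.15) and Pura, a nucleic acid binding protein gene, by 1.89 ± 0.08. Nfkbia, the inhibitor of NF-kB that NF-kB itself induces, rose from 371 ± 6.45 to 905 ± 8.39 FPKM (1.29 ± 0.20, adjusted p = 0.00628, and 0.0547 without LPS plus Sal-B replicate 2). Selenbp1 rose by 1.86 ± 0.25 after its fall of 3.36 ± 0.25 with LPS.

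**Figure D3:**
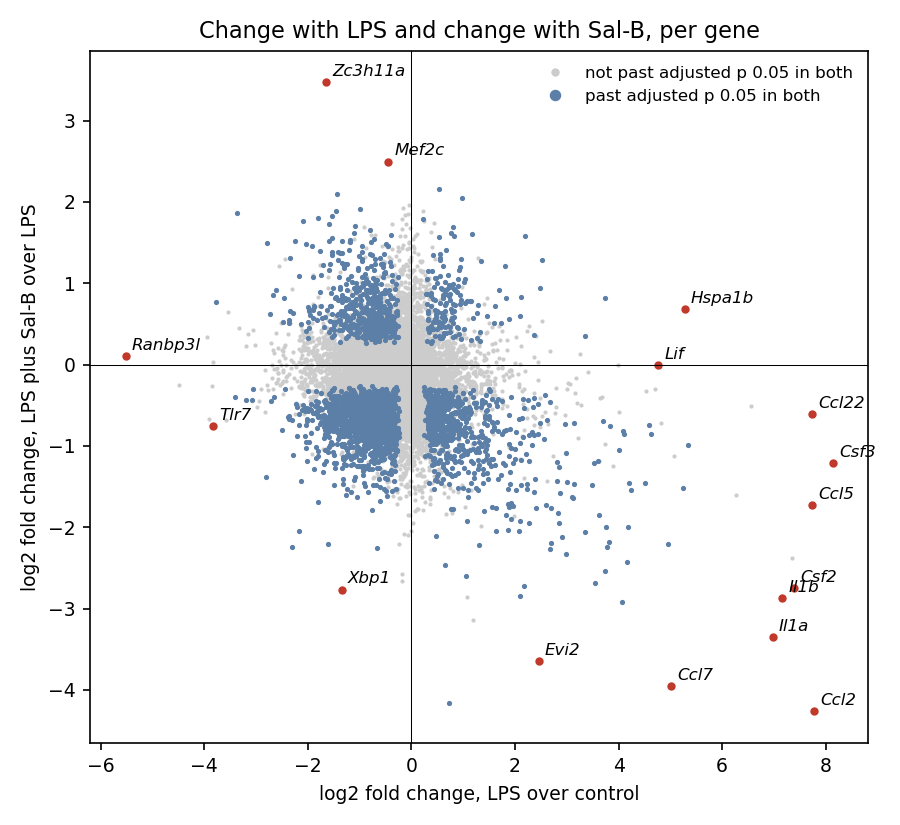
Log2 fold change with LPS against control and with LPS plus Sal-B against LPS for each gene tested. Ccl2, Il1a and Il1b lie far to the right and low, and both axes share the LPS libraries.

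Of 15 chemokine genes 10 fell and 0 rose with Sal-B, 13 and 0 adjusted over the list alone (camera adjusted p = 0.000267, adjusted p = 0.546 with an estimated correlation). Of 19 cytokine genes 15 fell and 0 rose, 16 and 1 adjusted over the list alone (adjusted p = 0.000471, 0.403 with an estimated correlation). The type I interferon list had 22 of 40 genes down and 1 up, 23 and 2 adjusted over the list alone (adjusted p = 0.0229, 0.751 with an estimated correlation), with Rtp4 down by 1.76 ± 0.11, Ifi204 by 1.57 ± 0.10 and Ifit2, an inhibitor of viral translation, by 1.73 ± 0.13. NF-kB feedback genes had 10 down and 1 up of 28, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.428). NRF2 targets and antioxidant genes had 22 of 33 down and 1 up, 24 and 1 adjusted over the list alone (adjusted p = 0.000267, 0.546 with an estimated correlation), with the thioredoxin gene Txn1 down by 0.86 ± 0.07 and the peroxiredoxin gene Prdx1 by 1.19 ± 0.10. Of this list 17 fell at the same median and 13 both under quantile normalization and at the same total, each with 1 up. Endoplasmic reticulum stress genes had 17 of 39 down and 2 up, 18 and 2 adjusted over the list alone (adjusted p = 0.0199, 0.688 with an estimated correlation). Macrophage identity and phagocytic receptor genes (28 gene IDs of 27 symbols, Itgam having 2) had 16 down and 1 up, also when adjusted over the list alone (adjusted p = 0.0265, 0.549 with an estimated correlation).

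Of 49 nuclear respiratory chain genes 40 fell and 1 rose with Sal-B, 42 and 1 adjusted over the list alone (camera adjusted p = 1.49e-06, adjusted p = 0.403 with an estimated correlation). The number that fell was 30 at the same median and 20 both under quantile normalization and at the same total. Ndufs4, a complex I subunit gene, fell by 1.15 ± 0.08, Cox6b1, of cytochrome c oxidase, by 1.06 ± 0.09 and Sdhd, of succinate dehydrogenase, by 0.89 ± 0.08. Of the 13 mitochondrially encoded genes 8 rose and 0 fell, 9 and 2 adjusted over the list alone (adjusted p = 2.75e-05, 0.403 with an estimated correlation), mt-Nd3 by 0.76 ± 0.08 and mt-Nd2 by 0.72 ± 0.08. Histone genes, whose mRNAs mostly lack a poly(A) tail, rose in the same comparison (15 up and 2 down of 26), so a difference in RNA capture between the treated groups was not excluded for this rise. The histone genes are also tied to cell division, and mitosis genes rose too, so the histone rise does not single out capture. Mitosis genes had 13 of 40 up and 3 down, the same when adjusted over the list alone (adjusted p = 5.23e-07, 0.546 with an estimated correlation), and 22 up and 0 down at the same median. Among them Cenpe, a kinetochore motor, rose from 7.96 ± 0.229 to 21.7 ± 0.206 FPKM (1.34 ± 0.09), Hmmr by 1.48 ± 0.10 and Top2a, which untangles DNA, by 1.10 ± 0.11. Glycolysis genes (25 gene IDs of 24 symbols, Aldoa having 2) had 8 up and 5 down, the same when adjusted over the list alone (adjusted p = 0.0162, 0.549 with an estimated correlation), with the hexokinase genes Hk1 and Hk2 up by 0.99 ± 0.08 and 0.74 ± 0.09. This split became 12 up and 2 down at the same median, and 11 and 1 both under quantile normalization and at the same total.

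**Figure D4:**
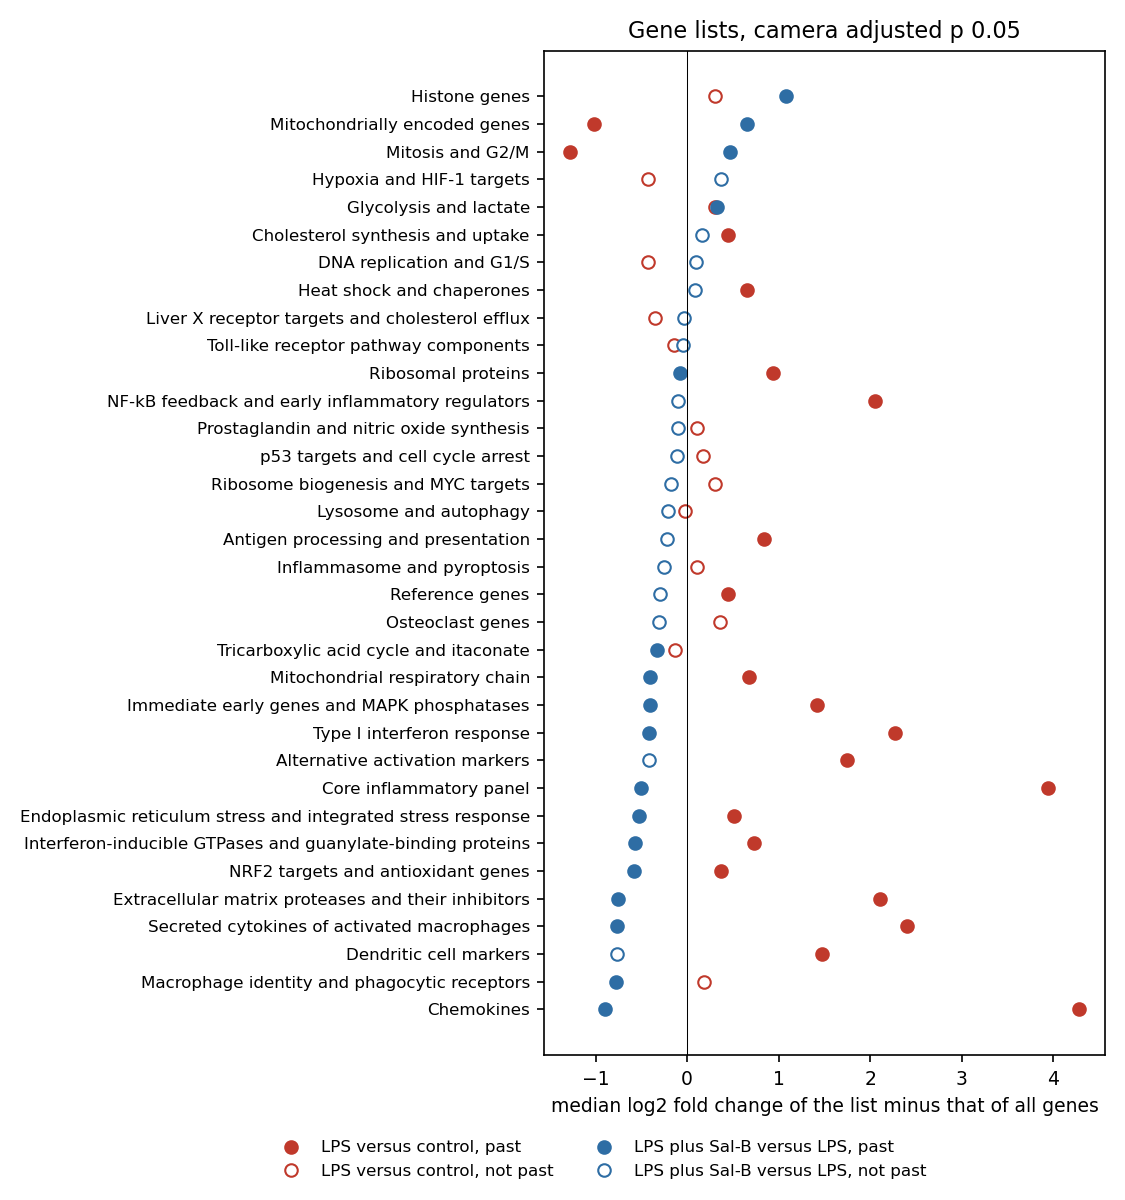
Median log2 fold change of each gene list tested against that of all genes, for LPS against control and for LPS plus Sal-B against LPS. Chemokine and cytokine genes rose in the first and fell in the second.

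Across all genes 1054 rose and 3184 fell with Sal-B against LPS alone (limma-trend, adjusted p < 0.05), 224 and 592 at least 2-fold. The same median gave 1721 up and 2090 down, the same total 1637 and 1730, and quantile normalization 1593 and 1653, and the median log2 fold change moved from −0.22 to −0.06 at the same median. The total of 4238 was sensitive to single libraries: it was 1866 without LPS replicate 2, 1974 without LPS replicate 3, 1043 without LPS plus Sal-B replicate 2 and 1297 without LPS plus Sal-B replicate 3. With each treated pair averaged to 1 sample the limma count was 0 up and 0 down, with 1481 genes at unadjusted p < 0.05. In that setting the spread comes from the control pair alone, the widest of the pairs (SD of the log2 difference 0.44 against 0.27 for LPS and 0.19 for LPS plus Sal-B), so the count of 0 does not tell that spread from the averaging.

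Genes such as Ccl2, Il1a, Il1b, Csf2, Tnf and Hmox1 rose with LPS and fell when Sal-B was added. In all, 618 genes went up with LPS and down with Sal-B, where 452 were expected from independent lists, and 502 went down and then up, where 516 were expected. The larger of these classes depended on scaling, with 293 up and then down (188 expected) and 925 down and then up (952 expected) at the same total, and with a library left out 618 became 184 (without LPS plus Sal-B replicate 2) to 1203 (without control replicate 2). With a change of at least 2-fold in both steps 130 genes went up and then down against 30.6 expected from independent lists. Part of this excess is built in. A gene below 1 FPKM with LPS cannot fall 2-fold on log2(FPKM + 1), and genes raised 2-fold lie above that level. The 1120 opposite changes stood beside 1644 genes that moved in the same direction in both steps, but the order turned with scaling: 1279 opposite against 1050 at the same median, 1218 against 1147 at the same total and 1078 against 731 after GC and length correction, while quantile normalization gave 937 against 952. Both comparisons use the LPS libraries, so error in those libraries alone pushes the fold changes apart. In 100 simulated sets without any change this sharing gave a mean r of −0.42 (lowest −0.49, highest −0.36) and a covariance of −0.018. The observed r was −0.19 and the observed covariance −0.098, lower than the simulated covariance by 0.080. The observed r cannot be set against the simulated r, because the real groups hold many changes and the simulated ones none. Splitting the LPS libraries between the comparisons, which removes the sharing, gave r of −0.151 and −0.149 and covariances of −0.081 and −0.079. With 1 LPS library used for each comparison, 389 and 393 opposite changes were counted, with 217 and 227 genes up and then down against 135 and 140 expected. The number 1120 became 2127 without control replicate 2, 1873 without control replicate 3, 435 without LPS replicate 2, 428 without LPS replicate 3, 276 without LPS plus Sal-B replicate 2 and 339 without LPS plus Sal-B replicate 3. It was 0 with the treated pairs averaged.

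Cells given LPS plus Sal-B still differed from control cells in the inflammatory direction for most mediators. Ccl22, Csf3, Ptgs2 and Ccl5 were far above control, as were Nos2 and the heat shock gene Hspa1b. The receptor genes Fcgr3 and Trem2 and the lysosomal gene Lamp1 were lower than in control. The protease gene Adam10, which sheds surface proteins, and the sialic acid receptor gene Cd33 were among the largest falls.

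Ccl22 stood at 349 ± 10.2 FPKM against 1.57 ± 0.926 in control (log2 fold change 7.14 ± 0.24), Csf3 at 186 ± 6.02 (6.93 ± 0.09, adjusted p = 8.90e-06), Ptgs2 at 462 ± 5.41 (6.04 ± 0.24) and Ccl5 at 798 ± 16.1 (6.01 ± 0.08). Phlda1 rose by 5.40 ± 0.20, Hspa1b by 5.96 ± 0.14, Mmp9 by 4.78 ± 0.08 and Lif by 4.76 ± 0.09. Nos2 rose by 3.70 ± 0.09, Tnf by 2.19 ± 0.34 (adjusted p = 0.00210), Il6 by 0.85 ± 0.16 (adjusted p = 0.00494) and Ccl2 by 3.51 ± 0.11 (adjusted p = 6.29e-05). Hmox1 remained above control by 0.93 ± 0.09 (adjusted p = 0.000370), and Cxcl10 by 2.24 ± 0.18. Hsp90aa1, a major chaperone gene, rose from 93.6 ± 33.9 to 572 ± 4.19 FPKM (2.65 ± 0.24) and Cdkn1a, which halts the cell cycle, from 44.1 ± 10.9 to 343 ± 2.75 (2.95 ± 0.17). Tlr4 fell by 1.72 ± 0.55 (adjusted p = 0.0336, but 0.0644 without LPS replicate 2 or LPS replicate 3, 0.100 without LPS plus Sal-B replicate 2, 0.108 without LPS plus Sal-B replicate 3 and 0.0648 at the same median) and Nlrp3 by 1.25 ± 0.10 (adjusted p = 0.000233).

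Adam10 fell from 84.1 ± 7.26 to 2.65 ± 0.282 FPKM (−4.54 ± 0.11, adjusted p = 4.02e-05), Cd33 from 94.2 ± 16.3 to 4.20 ± 0.108 (−4.18 ± 0.14), Fcgr3 from 25.6 ± 2.74 to 0.421 ± 0.0207 (−4.22 ± 0.11) and Xbp1 from 59.7 ± 10.6 to 2.5 ± 0.610 (−4.12 ± 0.17). Scel and Tlr9, a sensor of bacterial DNA, were listed at 0 in both LPS plus Sal-B libraries, against 19.0 ± 14.2 and 3.05 ± 0.391 FPKM in control (adjusted p = 0.000826 and 0.000130). Cat, which breaks down hydrogen peroxide, fell by 2.61 ± 0.10 and Nfe2l2, the NRF2 gene, by 2.10 ± 0.13. Trem2, a lipid-sensing receptor, fell by 3.00 ± 0.18, Lamp1, a lysosomal membrane protein gene, by 2.55 ± 0.14 and Nusap1, of the mitotic spindle, by 3.08 ± 0.15.

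The type I interferon list had 29 of 40 genes up and 2 down against control, also when adjusted over the list alone (camera adjusted p = 6.18e-17, adjusted p = 0.315 with an estimated correlation). Cytokine genes had 14 of 19 up and 1 down, also when adjusted over the list alone (adjusted p = 3.92e-13, 0.164 with an estimated correlation), and chemokine genes 11 of 15 up and 2 down, also when adjusted over the list alone (adjusted p = 2.23e-09, 0.31 with an estimated correlation). Heat shock genes had 9 of 20 up and 6 down, also when adjusted over the list alone (adjusted p = 0.00142, 0.31 with an estimated correlation). At the same median 14 of them rose and 3 fell, and quantile normalization gave 12 and 4. Mitosis genes had 36 of 40 down and 1 up, also when adjusted over the list alone (adjusted p = 0.00142, 0.676 with an estimated correlation). Their falls shrank to 22, with 4 up, at the same median and to 29, with 3 up, under quantile normalization. Respiratory chain genes had 26 of 49 down and 7 up, also when adjusted over the list alone, did not pass (adjusted p = 0.812) and flipped to 24 up and 11 down at the same median. Macrophage identity and phagocytic receptor genes had 15 of 28 gene IDs down and 5 up, also when adjusted over the list alone (adjusted p = 0.756, 13 down and 10 up at the same median). Lysosomal genes had 26 of 42 down and 5 up, also when adjusted over the list alone (adjusted p = 0.426, 17 down and 13 up at the same median). Across all genes 1399 rose and 5890 fell, 543 and 3224 at least 2-fold, against 3201 up and 3191 down at the same median, where the median log2 fold change moved from −0.63 to −0.02. With each treated pair averaged to 1 sample 578 rose and 3435 fell.

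On GRCm38, Ccl2 (ENSMUSG00000035385.5) lies on chromosome 11 at 82035571 to 82037453 (+) with Ccl7 (ENSMUSG00000035373.2) next to it at 82045712 to 82047525 (+), and Csf3 (ENSMUSG00000038067.2) on the same chromosome at 98701263 to 98703629 (+). Il1a (ENSMUSG00000027399.1) and Il1b (ENSMUSG00000027398.13) lie on chromosome 2 at 129299610 to 129309972 (−) and 129364570 to 129371139 (−). Ranbp3l (ENSMUSG00000048424.16) is at 8968002 to 9067335 (+) on chromosome 15, Mef2c (ENSMUSG00000005583.16) at 83504034 to 83667080 (+) on chromosome 13, Zc3h11a (ENSMUSG00000102976.5) at 133619862 to 133661380 (−) on chromosome 1, and mt-Nd3 (ENSMUSG00000064360.1) at 9459 to 9806 (+) of the mitochondrial genome.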

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

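Scaling to the same total, the GC and length correction, the averaging of treated pairs and the same-median gene lists were chosen after seeing the data, and the other alternatives were planned. Leaving out a library leaves its group with 1 library, which is then assumed to vary like the other groups.

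For LPS against control, 6319 genes changed in the values as reported. Requiring at least a 2-fold change left 2437, by construction, and averaging each treated pair to 1 sample left 1607, which removes 2 of the 3 residual degrees of freedom. Leaving out a library gave 4727 to 7162. For LPS plus Sal-B against control, 7289 genes became 3767 with the 2-fold minimum and 4013 with treated pairs averaged, and 5762 to 7997 with a library left out.

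For LPS plus Sal-B against LPS, 4238 genes became 816 with the 2-fold minimum and 0 with treated pairs averaged (limma, 1481 at unadjusted p < 0.05), a setting in which only the wide control pair gives the spread. Without LPS replicate 2 the count was 1866, without LPS replicate 3 it was 1974, without LPS plus Sal-B replicate 2 it was 1043 and without LPS plus Sal-B replicate 3 it was 1297, against 6241 and 6245 without control replicate 2 or 3. The control libraries enter this comparison only through the estimate of the spread. With only the LPS and LPS plus Sal-B libraries in the model the count was 6248, so including the control pair lowered it. Leaving out a control library likewise takes the wide pair from that estimate. Leaving out a treated library takes a close pair from it, but whether this alone caused the lower counts was not tested.

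The 1120 opposite changes became 177 with the 2-fold minimum, 0 with treated pairs averaged and 389 or 393 with the LPS libraries split between the comparisons. They ran from 276 without LPS plus Sal-B replicate 2 to 2127 without control replicate 2, with 339 without LPS plus Sal-B replicate 3, 428 and 435 without LPS replicate 3 or 2, and 1873 without control replicate 3. With only the libraries of each comparison in its model the number was 1380, beside 1939 changes in the same direction. The cause was not tested.

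Of the 20, 17 and 16 gene lists past the threshold in the 3 comparisons, in the order LPS against control, LPS plus Sal-B against LPS, and LPS plus Sal-B against control, 0, 0 and 0 passed when camera estimated the correlation between genes. The size of the correlation alone does not account for this in each list. With LPS against control, cytokine genes had an estimate of 0.0203, near the preset 0.01. Their camera adjusted p still went from 3.10e-18 to 0.122. The core inflammatory panel had an estimate of −0.0310, below the preset, and went from 3.92e-09 to 0.130. Other lists had larger estimates, such as 0.750 for ribosomal proteins. The 2 forms also differ in degrees of freedom. With an estimated correlation camera uses at most the residual ones of the model, 3 here. With a preset correlation it uses nearly as many as there are genes tested. A loss with an estimated correlation is therefore not by itself a sign of correlated genes. How much each difference contributed was not tested. Fry asks another question, whether a list changed at all rather than against the other genes, so a shift of all genes counts in it. It called 23, 27 and 27 lists, and 4, 2 and 4 of the lists called by camera were not among them. Leaving out a library gave 18 to 23, 16 to 19 and 15 to 18 lists. Of the lists called as reported, quantile normalization lost 7, 1 and 5, the pseudocount of 0.1 lost 0, 4 and 0, the same median lost 2, 1 and 3, and the GC and length correction lost 2, 3 and 2, and the cause was not tested. Leaving out a library lost at most 3 of 20 (without control replicate 3), 1 of 17 and 1 of 16, and in these alternatives 0 lists passed in the opposite direction.

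Over all alternatives, 1 named gene that passed in an alternative changed direction: mt-Atp6 with LPS against control stood at −0.01 as reported and 0.52 at the same median (adjusted p = 0.0201, over its alternatives 7.91e-05 to 0.987). In that setting each library is multiplied by its own factor, which raises the LPS libraries against control.

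The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at r = 0.01 between control and LPS, 0.00 between control and LPS plus Sal-B, and 0.03 between the treated groups. With the replicate block 6086, 3822 and 7195 genes changed in the 3 comparisons, in the same order, and 962 changes were opposite.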

Other observations

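Single receptor and lipid transport genes fell with LPS beside the inflammatory program, but the lists they belong to did not pass. Of 27 Toll-like receptor pathway genes, 12 fell and 4 rose with LPS, also when adjusted over the list alone, the list did not pass (camera adjusted p = 0.845), and 7 rose and 7 fell at the same median. Tlr7, Tlr13 and Tlr9, the sensors of nucleic acids in endosomes, were the members with the smallest p. Lysosomal genes had 22 of 42 down and 6 up with LPS, also when adjusted over the list alone (adjusted p = 0.649), but 13 up and 8 down at the same median. Liver X receptor targets, which export cholesterol, had 8 of 13 down and 2 up, or 9 and 2 adjusted over the list alone (adjusted p = 0.223), with the transporter gene Abcg1 down by 1.99 ± 0.09 and Pltp, which transfers phospholipids, by 1.39 ± 0.10. Ptgs1, the constitutive cyclooxygenase, fell from 29.5 ± 8.04 to 2.36 ± 0.193 FPKM (SD, n = 2), opposite to Ptgs2. The list of both, prostaglandin and nitric oxide synthesis, had 6 up and 8 down of 18 with LPS and did not pass (camera adjusted p = 0.224). At the same median 8 rose and 5 fell.

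With Sal-B against LPS, Casp1, which cleaves interleukin-1 precursors, fell from 54.0 ± 4.11 to 20.6 ± 1.25 FPKM. Its list, inflammasome and pyroptosis genes, had 7 of 14 down and 0 up and did not pass (camera adjusted p = 0.0672). Dcstamp and Acp5, genes of osteoclast fusion and bone resorption, fell by 1.23 ± 0.14 and 1.45 ± 0.11 in the same comparison. Their list, osteoclast genes, had 8 of 14 down and 1 up, 8 and 2 adjusted over the list alone, and did not pass (camera adjusted p = 0.246, adjusted p = 0.549 with an estimated correlation). Replication-dependent histone genes had 15 of 26 up and 2 down, 18 and 2 adjusted over the list alone (camera adjusted p = 4.90e-08, adjusted p = 0.403 with an estimated correlation). This list was fixed as a check of poly(A) selection, and since the labels do not give the capture method of each library, a capture difference between the treated groups was not excluded for its rise. Mitosis genes rose in the same comparison (13 of 40 up and 3 down), so a change in cell division was not excluded either. Hist1h1e, a linker histone gene, rose from 7.08 ± 0.623 to 17.5 ± 0.119 FPKM. Hist1h2ao rose from 127 ± 1.35 to 475 ± 11.4, although fragments of near-identical histone genes are hard to assign and its adjusted p was 0.0542 to 0.0612 without any 1 of the LPS or LPS plus Sal-B libraries.

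Tests chosen only after the result was seen were the carry-over test below and the tests of other explanations for the falls with Sal-B and for the changes of the mitochondrially encoded genes, and the tests of short genes and of RNA capture were revised after a first outcome.

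Control replicate 2 read higher than control replicate 3 in 373 of the 517 genes that LPS raised at least 2-fold (72.1%, against 55.0% of all genes tested). Carry-over of an LPS library would add the same share of its LPS level to each gene, but in 24 strongly induced genes, 21 of them higher in replicate 2, the excess ran from a lower quartile of 0.0636% to an upper quartile of 4.50% of that level. GC percent and transcript length left a median log2 excess of 0.189 after correction, against 0.227 before. A mild activation of the cells of control replicate 2 remains a candidate explanation, and no biological explanation was tested because the design gives none within a group.

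Chemokine and cytokine genes fell with Sal-B against LPS. They stayed past the threshold after the GC and length correction (camera, larger adjusted p of the 2 lists 0.000278), which argues against those trends as the whole cause. They also passed at the same median (0.000133). That outcome cannot test scaling, because camera sets a list against the other genes and a library factor moves all genes almost alike. Gene by gene at the same median, 8 of 15 chemokine genes fell and 0 rose, and 14 of 19 cytokine genes fell and 1 rose. A share of cells that did not respond to LPS would leave each gene at the same percentage, but the percentage kept had an upper quartile of 62.9 and a lower quartile of 16.7. These unequal shares bear on that explanation only. A gene-selective effect of Sal-B on the LPS response remains a hypothesis, found and tested on the same 2 libraries per group. With a single LPS dose and no treatment time given, it cannot be told apart from a weaker or later response as a whole. No group was given Sal-B without LPS, so effects of Sal-B that do not depend on LPS cannot be told apart either. With the treated pairs averaged 0 genes passed limma (1481 at unadjusted p < 0.05), but each treated group then holds 1 sample and the spread comes from the control pair alone, so that setting neither supports nor excludes the falls. Neither list passed with an estimated correlation (0.546 and 0.403).

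The 13 mitochondrially encoded genes moved apart with LPS although most of them are made from a shared precursor transcript. A scaling factor would move them alike, but their log2 changes spanned 4.12. Loss of short fragments would move only short genes, but genes of 900 nucleotides or more spanned 2.72. Another RNA capture in the LPS libraries and a change in mitochondrial RNA cannot be told apart: 53 histone genes, whose mRNAs mostly lack a poly(A) tail, had a median log2 change of 0.266 above that of all genes, with quartiles of −0.47 and 0.68, and a class that moves both ways leaves this open. Histone genes are also tied to cell division, and all 40 mitosis genes fell with LPS, so they do not mark capture alone.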
